A study of Mus musculus with 12 samples.

How the data were processed

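Total RNA of mouse liver was sequenced, per the labels, after extraction with a column kit (RNeasy) and library preparation from 1 μg of RNA with a NEBNext Ultra RNA kit. Whether poly(A) selection or rRNA depletion was used, and whether the libraries kept strand, is not given in the sources used here. The 12 samples are 6 livers on a control diet and 6 on a ketogenic diet, and the series design calls them biological replicates. Composition and length of the diets, age, sex, strain and hour of collection are not given in the sources used here. The authors deposited 1 table of raw counts, whole-number read counts per gene for each library with no normalization, beside gene symbols, biotypes, coordinates and GO terms. Tools named in the submitters' processing notes, with no role stated, are fastp 0.19.3, HISAT2 2.1.0, StringTie 1.3.4d and Cufflinks. The program that counted reads, its strand setting, the annotation release and the genome build are not given in the sources used here. Of 26929 gene IDs found in a GENCODE annotation of GRCm38, 569 had the same start and end as in the deposited table. Coordinates are therefore printed as the table gives them and no build is assigned. Genes that overlap, antisense partners and near copies (the Cyp2b, Cyp4a, Mup, Saa, Orm, hepcidin, thiolase and haemoglobin genes) can share reads, and their values are uncertain to that extent.

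The table held 27105 genes with at least 1 count in all, 18742 of them protein-coding and 5848 lncRNA genes; 45 had an ID and no symbol and are named by ID. Library totals were 30.2 to 33.5 M counts. Molecular identifiers are not given in the sources used here, so amplification copies are counted. In each diet, chi-square tests of all pairs of libraries over genes with at least 50 counts found no duplicates (lowest chi-square per degree of freedom 40.8). The median biological coefficient of variation was 0.213.

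Diets were compared with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by diet, which left 13995, scaled with TMM factors, and tested with the robust quasi-likelihood fit (glmQLFit, glmQLFTest) with diet as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. Before the data were examined, 40 gene lists were fixed for lipid, carbohydrate, amino acid and drug metabolism, mitochondria, stress, inflammation, the cell cycle and the clock, other cell types, liver zones, sex and ribosomes. Each list with at least 3 tested members was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Members were also counted after adjustment over the list alone. Camera with an estimated correlation and fry (rotation test) were run as alternatives. Shares of counts per library were compared with two-sided exact permutation tests over all 924 splits of the 12 libraries.

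The genes named were set by a rule fixed before the data were examined. It takes the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM, no overlap between the diets and a proper symbol. It adds 12 genes fixed for their place in ketone, lipid, glucose and bile acid metabolism (among them Bdh1, Cpt1a, Pdk4, Fgf21, Srebf1, Fasn, Pnpla3, Pck1, Cyp7a1 and Cdkn1a) and up to 3 members of each list with the smallest p. It gave 134 genes, of which 71 were called. Another 58 genes, 49 of them called, were chosen after their values were seen, and those named are said to be so. Some genes are not reported here.

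The steps were tested on simulated counts for 13797 genes with the means and library sizes of this comparison and 200 changed genes. Of these, 74 of 100 genes changed by a log2 of 1 and 98 of 100 changed by a log2 of 2 were called. In all, 10 of 182 calls were unchanged genes. Camera called 0 lists without a change and the list that was shifted. Each gene was drawn on its own, so the simulation cannot show how camera behaves when genes of a list are correlated. Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE factors, library size only, no filter on low counts, at least 1 CPM in 6 samples, an adjusted p under 0.01, and a test against a 1.2-fold change. The others were the replicate number as a block, 1 surrogate variable from svaseq (sva 3.50.0), removal of the 10 most abundant genes, and each library left out. Chosen after the data were seen were the removal of each library's trend on transcript length (a smoothing spline with 4 degrees of freedom, used as offsets) and the same with the block. So were list counts without ketogenic diet replicate 4, the scores of clock and cholesterol genes, and tests of GO terms. Transcript lengths and GC content came from the GRCm38 annotation by gene ID, for 13972 (99.8%) of the genes tested. GO terms with 10 to 500 tested genes, as the deposited table pairs them, were tested with a hypergeometric test against the tested genes that have a GO term. No sample was left out.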

Results

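RNA of mouse liver was sequenced from animals on a control diet and from animals on a ketogenic diet, a diet low in carbohydrate and high in fat under which the liver makes more ketone bodies. Each diet had 6 libraries, described in the series design as biological replicates. Libraries are named below by diet and replicate number (control 1, ketogenic 4). The libraries held 30.2 to 33.5 M (mega) counts over 27105 genes, and 18306 to 21938 genes had at least 1 count in a library. Albumin, the main plasma protein made by hepatocytes, took 6.60% of all counts.

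The share of transcripts of the mitochondrial genome was 3.66 ± 0.429% of counts on the control diet against 3.30 ± 0.623% on the ketogenic diet (exact p = 0.266). Mup genes, which code for major urinary proteins, took 2.02 ± 0.626% against 2.21 ± 0.686% (exact p = 0.632), haemoglobin genes 0.00329 ± 0.00155% against 0.00468 ± 0.00228% (exact p = 0.253) and the 10 most abundant genes 17.0 ± 1.17% against 15.8 ± 0.912% (exact p = 0.0736). Library size was 31.7 ± 1.31 against 32.7 ± 0.937 M counts (exact p = 0.173). Values are mean ± SD with n = 6, the p-values come from two-sided exact permutation tests over 924 splits, and the lowest of the 5 after Benjamini-Hochberg adjustment was 0.333. Ketogenic 4 stood apart from the other ketogenic libraries, with a median correlation of 0.951 to its own group against 0.978 to 0.984. Short transcripts were high and long transcripts low in that library, with a Spearman rho of -0.551 across genes between its deviation from the other libraries and transcript length, against -0.325 to 0.354 in the other libraries.

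**Figure D1:**
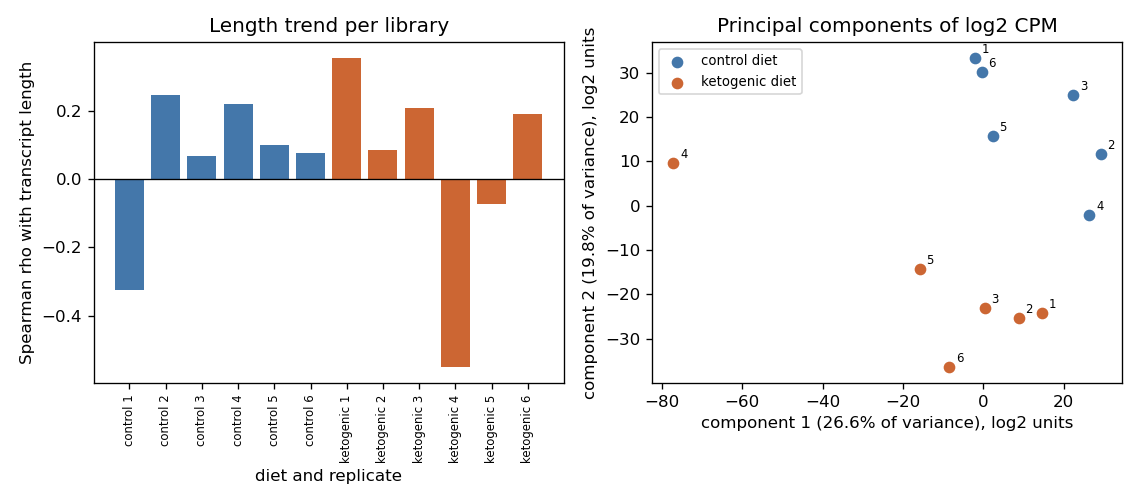
Left, Spearman rho across genes between each library's deviation from the other libraries and transcript length, 1 bar per library. Right, scores of the 12 libraries on principal component 1 (26.6% of the variance of log2 CPM) and 2 (19.8%); ketogenic 4 lies at -77.1 on component 1.

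The comparison asks how gene expression in the liver differs after a ketogenic diet. On the ketogenic diet, most genes of cholesterol synthesis and uptake rose (18 of 26 tested), as did smaller parts of the genes of mitochondrial (7 of 21) and peroxisomal fatty acid oxidation (4 of 19) and of lipid droplets and fatty acid uptake (5 of 21). Camera called these 4 lists as higher with a preset correlation and none of them with an estimated correlation (adjusted p = 0.125, 0.330, 0.363 and 0.363). The cytochrome P450 genes Cyp2b10 and Cyp4a14 rose too. Among the genes that fell were Scd1, the main stearoyl-CoA desaturase of liver, from 11078 ± 6239 to 884 ± 412 CPM (mean ± SD, n = 6), the pyruvate kinase gene Pklr from 424 ± 90.6 to 134 ± 18.5 CPM and the ketohexokinase gene Khk from 618 ± 76.6 to 245 ± 62.7 CPM. Fibrinogen and hepcidin genes and several secreted liver proteins fell as well. Of the genes of ketone body metabolism, Bdh1, which makes beta-hydroxybutyrate, rose from 274 ± 48.6 to 568 ± 56.5 CPM (log2 fold change 1.05 ± 0.13, adjusted p = 0.000409).

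Of 13995 genes tested with edgeR's quasi-likelihood test, 328 rose and 201 fell at a Benjamini-Hochberg adjusted p under 0.05, 529 in all, of which 504 were protein-coding and 23 were lncRNA genes. The change was at least 1 on the log2 scale for 147 of the genes that rose and 74 of those that fell. With library size as the scale in place of TMM factors, which moves the median of all genes by 0.07, 448 rose and 127 fell, so that 77.9% of the calls were rises against 62.0%. Without ketogenic 4, 445 genes rose and 316 fell, with 485 of the 529 kept. Among the fits with 1 library left out, the count was lowest without control 3, at 213 and 106. In each of the 71 genes of the naming rule that passed the threshold, all 6 ketogenic libraries lay on the same side of the control mean. The rule itself asks this of 16 of them, and passing the threshold makes it likely for the rest. It is therefore no separate support. Gene fold changes below are log2 ketogenic over control ± SE, with adjusted p from edgeR, and CPM levels are mean ± SD with n = 6 per diet, control first.

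The largest rise was that of Cyp2b10 (ENSMUSG00000030483, chromosome 7, 25597045 to 25626049, in the coordinates of the deposited table, whose genome build is not given in the sources used here). Cyp2b10, a cytochrome P450 gene known as a target of the receptor CAR, went from 0.0885 ± 0.0691 to 10.9 ± 4.48 CPM, a log2 fold change of 6.85 ± 0.47, adjusted p = 7.65e-06. Cfd (ENSMUSG00000061780, chromosome 10, 79726687 to 79728489), which encodes the complement factor adipsin, went from 0.192 ± 0.145 to 9.84 ± 11.3 CPM (5.67 ± 1.05, adjusted p = 0.00946), with ketogenic libraries between 0.511 and 29.2 CPM and no call under limma-voom (adjusted p = 0.147, in a range of 1.02e-07 to 0.147 over its alternatives). Slc35f2 (ENSMUSG00000042195, chromosome 9, 53678822 to 53725438) rose by 4.02 ± 0.49 (adjusted p = 0.000425) and Cidec (ENSMUSG00000030278, chromosome 6, 113401595 to 113412721), a lipid droplet protein, from 8.19 ± 4.12 to 97.9 ± 58.2 CPM (3.58 ± 0.48, adjusted p = 0.00135). Mogat1 (ENSMUSG00000012187, chromosome 1, 78487628 to 78514810), a monoacylglycerol acyltransferase, rose by 3.04 ± 0.43 (adjusted p = 0.00141) to a low level of 2.02 ± 1.201 CPM. Osbpl3 (ENSMUSG00000029822, chromosome 6, 50270310 to 50433181), of the oxysterol-binding protein family, rose from 1.95 ± 0.973 to 16.1 ± 8.66 CPM (3.03 ± 0.40, adjusted p = 0.00103). Pnldc1 (ENSMUSG00000073460, chromosome 17, 13107616 to 13129117), a nuclease known from the trimming of piRNAs, and the keratin gene Krt23 (ENSMUSG00000006777, chromosome 11, 99368800 to 99383963) rose by 2.84 ± 0.41 (adjusted p = 0.00147) and 2.76 ± 0.37 (adjusted p = 0.00103). Cyp2b10 shares sequence with the other Cyp2b genes, so its count is uncertain where reads fit several of them.

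The largest fall was that of Hamp2 (ENSMUSG00000056978, chromosome 7, 30621797 to 30624106), a copy of the hepcidin gene whose reads can be shared with Hamp, from 6.93 ± 4.48 to 0.358 ± 0.0776 CPM (-4.26 ± 0.46, adjusted p = 0.000226). Pnpla3 (ENSMUSG00000041653, chromosome 15, 84052038 to 84071437), a lipid droplet hydrolase, fell from 2.95 ± 1.46 to 0.182 ± 0.131 CPM (-3.99 ± 0.46, adjusted p = 0.000306), and Slc34a2 (ENSMUSG00000029188, chromosome 5, 53195423 to 53229006), a sodium-phosphate cotransporter, from 9.03 ± 3.92 to 0.575 ± 0.320 CPM (-3.96 ± 0.38, adjusted p = 0.000154). Scd1 (ENSMUSG00000037071, chromosome 19, 44382894 to 44396318) fell by 3.65 on the log2 scale (SE 0.42, adjusted p = 0.000368). Atp2b2 (ENSMUSG00000030302, chromosome 6, 113720792 to 114019574), a calcium pump of the plasma membrane, fell from 19.7 ± 7.82 to 2.40 ± 1.498 CPM (-3.03 ± 0.38, adjusted p = 0.000760). Plcxd1 (ENSMUSG00000064247, chromosome 5, 110247835 to 110253819), Trhde (ENSMUSG00000050663, chromosome 10, 114234726 to 114638212), which codes for an enzyme that degrades thyrotropin-releasing hormone, and the kinase gene Ttbk1 (ENSMUSG00000015599, chromosome 17, 46753374 to 46798601) fell by 2.29, 2.19 and 2.16 on the log2 scale (adjusted p = 0.000177, 0.00550 and 0.000425).

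**Figure D2:**
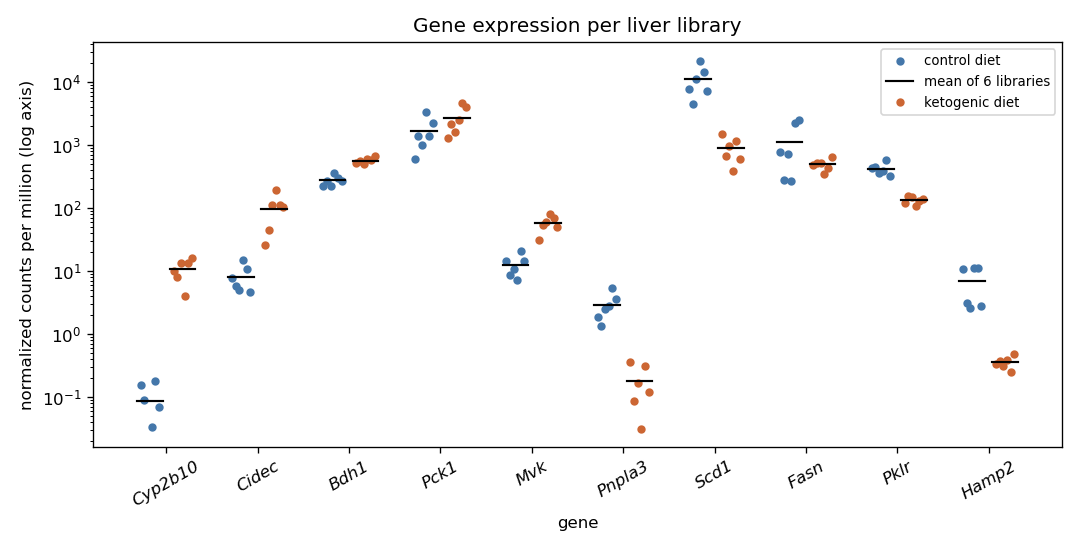
Normalised counts (CPM, log axis) of 10 genes in each of the 12 libraries, 1 point per library, with a bar at the mean of 6. For Cyp2b10, 1 control library with 0 counts is not drawn on the log axis.

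Among 10 genes of ketone body metabolism, 3 rose, 1 fell and 6 did not pass the threshold. With p adjusted over the list alone, 4 rose and 3 fell. The transporter gene Slc16a6, known for the export of beta-hydroxybutyrate, fell (-1.33 ± 0.21, adjusted p = 0.00271). Beside Bdh1, Acat1, chosen after its values were seen, rose (0.75, adjusted p = 0.0275). As a list they were not past the threshold (median log2 fold change 0.25, camera adjusted p = 0.261, and adjusted p = 0.548 with an estimated correlation). The call of Acat1 was lost without control 1 or 3 or ketogenic 2, 3, 5 or 6 (adjusted p 0.0121 to 0.0709 over the 12 fits).

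Of 21 enzymes of mitochondrial beta-oxidation tested, 7 rose, 0 fell and 14 did not pass the threshold. By p adjusted over the list alone, 17 rose and 0 fell (median log2 fold change 0.38, camera adjusted p = 3.80e-14, and adjusted p = 0.330 with an estimated correlation). The medium-chain acyl-CoA dehydrogenase gene Acadm rose from 371 ± 62.0 to 666 ± 90.5 CPM (0.84 ± 0.13, adjusted p = 0.00219), Acadl rose by 0.70 ± 0.11 (adjusted p = 0.00241) and Acads by 0.71 ± 0.12 (adjusted p = 0.00456). Acadvl, Hadhb, Hadh and Eci1, chosen after their values were seen, rose as well (log2 0.44, 0.64, 0.56 and 0.90), Acadvl not without control 1 or 3 or ketogenic 2 or 6 (adjusted p 0.00392 to 0.0580 over the 12 fits). Cpt1a, the gate of fatty acid entry into mitochondria, was at 0.38 ± 0.25, adjusted p = 0.520, and was not called. All 7 calls remained without ketogenic 4 and 6 of them with the length trend removed.

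Of 19 genes of peroxisomal fatty acid oxidation, 4 rose, 0 fell and 15 did not pass the threshold. Counted with p adjusted over the list alone, 7 rose and 0 fell (median log2 fold change 0.33, camera adjusted p = 2.26e-07, and adjusted p = 0.363 with an estimated correlation). The thiolase genes Acaa1a and Acaa1b, which are near copies and may share reads, rose by 1.08 ± 0.15 and 1.297 ± 0.25 (adjusted p = 0.00125 and 0.00915), and Decr2 by 0.92 ± 0.196 (adjusted p = 0.0171). Hsd17b4, chosen after its values were seen, rose by 0.58 (adjusted p = 0.0215). The call of Decr2 was lost without control 3 (adjusted p 0.00285 to 0.0507 over the 12 fits). That of Hsd17b4 was lost without ketogenic 2 (adjusted p 0.00931 to 0.0529 over the 12 fits).

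Of 18 other targets of PPAR-alpha, the fatty acid receptor that governs the fasting response of liver, 6 rose, 0 fell and 12 did not pass the threshold. If adjusted over the list alone, 8 rose and 0 fell (median log2 fold change 0.69, camera adjusted p = 5.00e-08, and adjusted p = 0.335 with an estimated correlation). The uncoupling protein gene Ucp2 rose from 46.8 ± 8.93 to 149 ± 46.8 CPM (1.67 ± 0.19, adjusted p = 0.000306), the fatty aldehyde dehydrogenase gene Aldh3a2 from 379 ± 140.3 to 1143 ± 70.5 CPM (1.59 ± 0.198, adjusted p = 0.000536) and the fatty acid hydroxylase gene Cyp4a14 from 826 ± 336 to 2973 ± 796 CPM (1.85 ± 0.25, adjusted p = 0.00105), the last with reads that paralogs of the Cyp4a family may share. Vnn1, Slc27a1 and Cyp4a10, chosen after their values were seen, rose by 1.54, 1.53 and 1.51. Neither Fgf21, a liver hormone of the fasting response, at -0.99 ± 0.50, adjusted p = 0.351, nor Pdk4, the kinase that turns off pyruvate dehydrogenase, at -0.30 ± 0.99, adjusted p = 0.932, passed the threshold. Pdk4 ran from 4.41 to 313 CPM over the control and from 10.025 to 243 CPM over the ketogenic libraries. In both diets, replicates 1 to 3 lay below replicates 4 to 6 in this gene. With such a spread the test cannot show that Pdk4 did not respond. With the replicate number as a block, Pdk4 was not called either. The call of Cyp4a10 was lost in 10 of the 12 leave-one-out fits, without control 1, 2, 3, 5 or 6 or ketogenic 1, 2, 3, 5 or 6 (adjusted p 0.000224 to 0.0751).

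Among 21 genes of lipid droplets and fatty acid uptake, 5 rose, 0 fell and 16 did not pass the threshold. When adjusted over the list alone, 7 rose and 0 fell (median log2 fold change 0.33, camera adjusted p = 0.000121, and adjusted p = 0.363 with an estimated correlation). Cd36, a fatty acid translocase, rose from 49.6 ± 10.4 to 177 ± 51.0 CPM (1.83 ± 0.198, adjusted p = 0.000226), next to Cidec and Mogat1. Pparg, a nuclear receptor that drives fat storage, and Fitm1, both chosen after their values were seen, rose by 1.39 (adjusted p = 0.00245) and 1.55 (adjusted p = 0.00257). All 5 calls were kept without ketogenic 4.

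Genes on the list of de novo lipogenesis went both ways, with the desaturase genes Fads1 and Fads2 as the only ones called higher over all genes. Of 21 tested, 2 rose, 4 fell and 15 did not pass the threshold. With p adjusted over the list alone, 3 rose and 6 fell (median log2 fold change -0.51, camera adjusted p = 0.0267, and adjusted p = 0.548 with an estimated correlation). Scd1 and Pnpla3 had the largest falls, and Elovl6 and G6pdx, chosen after their values were seen, fell by 0.94 and 0.80 on the log2 scale (adjusted p = 0.0174 and 0.0231). The fatty acid desaturase gene Fads2 rose from 697 ± 197 to 1596 ± 309.7 CPM (1.195 ± 0.185, adjusted p = 0.00229), and its neighbour Fads1, also chosen after its value was seen, rose by 0.70 (adjusted p = 0.0141). Neither the fatty acid synthase gene Fasn, at -1.19 ± 0.51, adjusted p = 0.255, nor Srebf1, which encodes the regulator SREBP-1, at -0.84 ± 0.35, adjusted p = 0.227, was called. As a list, the call was lost without control 5 or ketogenic 1 or 4 (adjusted p 0.00212 to 0.1996 over the 12 fits; without ketogenic 4 the median was -0.47), and that of G6pdx without control 5 or ketogenic 2 or 5 (adjusted p 0.00342 to 0.0550).

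Cholesterol synthesis and uptake was the list with the highest median change. Of 26 genes tested, 18 rose, 0 fell and 8 did not pass the threshold. By p adjusted over the list alone, 23 rose and 0 fell (median log2 fold change 1.64, camera adjusted p = 1.17e-26, and adjusted p = 0.125 with an estimated correlation). The mevalonate kinase gene Mvk rose from 12.6 ± 4.86 to 57.5 ± 17.0 CPM (2.18 ± 0.26, adjusted p = 0.000425), Nsdhl from 28.5 ± 13.5 to 116 ± 23.1 CPM (2.02 ± 0.27, adjusted p = 0.00103) and Dhcr7, the last enzyme of a branch of the pathway, from 48.6 ± 16.9 to 155 ± 35.4 CPM (1.67 ± 0.22, adjusted p = 0.000978). Among members chosen after their values were seen, Msmo1 rose by 2.56, Hmgcs1 by 2.46, Idi1 by 2.31, Lss by 1.92 and Cyp51 by 1.87. Without ketogenic 4, 15 of the 18 remained called. Fdps and Mvd, also chosen after their values were seen, rose by 1.90 and 2.20. The call of Fdps was lost without control 1, 2, 3 or 5 or ketogenic 1, 2, 3, 4, 5 or 6 (adjusted p 0.0221 to 0.102 over the 12 fits). That of Mvd was lost without control 1, 2, 3 or 4 or ketogenic 2, 3, 4, 5 or 6 (adjusted p 0.0161 to 0.0782 over the 12 fits). Over these fits the log2 fold change ran from 1.67 to 2.18 for Fdps and from 2.01 to 2.58 for Mvd.

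Of 21 genes of lipoprotein assembly and sterol efflux, 0 rose, 2 fell and 19 did not pass the threshold. Counted with p adjusted over the list alone, 0 rose and 2 fell (median log2 fold change -0.06, camera adjusted p = 0.312, and adjusted p = 0.548 with an estimated correlation). The lipoprotein lipase inhibitor Angptl8 fell from 192 ± 125 to 37.5 ± 22.9 CPM (-2.36 ± 0.56, adjusted p = 0.0358). Bile acid genes held few calls: of 21 tested, 1 rose, 1 fell and 19 did not pass the threshold, and 2 rose and 0 fell without ketogenic 4. If adjusted over the list alone, 3 rose and 1 fell (median log2 fold change 0.11, camera adjusted p = 0.370, and adjusted p = 0.688 with an estimated correlation). The transporter gene Abcc3 rose from 149 ± 60.9 to 331 ± 71.6 CPM (1.16 ± 0.25, adjusted p = 0.0194), and Cyp2c70, which makes muricholic acids in mice, fell from 457 ± 157 to 179 ± 89.4 CPM (-1.36 ± 0.33, adjusted p = 0.0357). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.93 ± 0.59, adjusted p = 0.498, and Cyp8b1, the sterol hydroxylase that makes cholic acid, at 1.10 ± 0.30, adjusted p = 0.0543, neither past the threshold. The call was lost for Angptl8 without control 1, 3 or 5 or ketogenic 1, 2, 3, 5 or 6 (adjusted p 0.0102 to 0.0815 over the 12 fits). That of Cyp2c70 was lost without control 1, 2, 3 or 6 or ketogenic 1, 3 or 4 (adjusted p 0.0222 to 0.0798 over the 12 fits). A call was gained for Cyp7a1 without control 5 (adjusted p 0.0407 to 0.711 over the 12 fits). That of Cyp8b1 was gained without ketogenic 1 (adjusted p 0.0452 to 0.128 over the 12 fits).

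The calls among genes of glycolysis and fructose use were all falls. Of 19 tested, 0 rose, 6 fell and 13 did not pass the threshold. When adjusted over the list alone, 0 rose and 6 fell (median log2 fold change -0.14, camera adjusted p = 0.00204, and adjusted p = 0.502 with an estimated correlation). Pklr had a log2 fold change of -1.66 ± 0.15, adjusted p = 6.80e-05, Khk, which phosphorylates fructose, of -1.33 ± 0.16, adjusted p = 0.000402, and Gckr, a regulatory protein of hepatocytes, of -0.50 ± 0.09, adjusted p = 0.00862. Gpi1, chosen after its values were seen, fell by 0.66 on the log2 scale.

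Of 19 genes of gluconeogenesis and glycogen, 0 rose, 3 fell and 16 did not pass the threshold. Without ketogenic 4, 0 rose and 5 fell. With p adjusted over the list alone, 1 rose and 5 fell (median log2 fold change -0.33, camera adjusted p = 0.0211, and adjusted p = 0.419 with an estimated correlation). Ppp1r3b, which targets protein phosphatase 1 to glycogen, fell from 509 ± 187 to 215 ± 57.7 CPM (-1.24 ± 0.25, adjusted p = 0.0137), the glycogen phosphorylase gene Pygl by 0.62 on the log2 scale (SE 0.13, adjusted p = 0.0167) and the fructose bisphosphatase gene Fbp1 by 0.57 (SE 0.13, adjusted p = 0.0206). Pck1, the gene of cytosolic PEPCK, was at 0.68 ± 0.40, adjusted p = 0.455, short of the threshold. The list lost its call without control 5 or ketogenic 1 or 3 (adjusted p 0.00850 to 0.0660 over the 12 fits), as did Fbp1 without control 1 or 2 or ketogenic 3 (adjusted p 0.0104 to 0.0581 over the 12 fits).

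Among 36 genes of the urea cycle and amino acid catabolism, 1 rose, 3 fell and 32 did not pass the threshold. By p adjusted over the list alone, 4 rose and 6 fell (median log2 fold change -0.11, camera adjusted p = 0.175, and adjusted p = 0.793 with an estimated correlation). Hal, Gls2 and Sds, which degrade histidine, glutamine and serine, fell by 0.76, 0.64 and 0.64 on the log2 scale (adjusted p = 0.0182, 0.0337 and 0.0444), and Gpt2, chosen after its value was seen, rose by 0.65 (adjusted p = 0.0494). In Hal and Gls2 the lowest ketogenic library was ketogenic 4. The list passed the threshold without control 6 (adjusted p 0.0212 to 0.415 over the 12 fits). Calls were lost for Hal without control 3 (adjusted p 0.00262 to 0.0528 over the 12 fits). That of Gls2 was lost without control 1, 2, 3 or 4 or ketogenic 1, 2, 3 or 5 (adjusted p 0.0134 to 0.0777 over the 12 fits). The same held for Sds without control 1, 2, 3, 4 or 5 or ketogenic 1, 2, 3 or 5 (adjusted p 0.0180 to 0.105 over the 12 fits). Gpt2 kept its call in only 2 of the 12 fits, those without ketogenic 1 and without ketogenic 4 (adjusted p 0.0289 to 0.121).

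Of 32 genes of xenobiotic metabolism, 4 rose, 0 fell and 28 did not pass the threshold. Counted with p adjusted over the list alone, 5 rose and 3 fell (median log2 fold change 0.13, camera adjusted p = 0.188, and adjusted p = 0.729 with an estimated correlation). Beside Cyp2b10, Cyp2b9 rose from 0.347 ± 0.512 to 30.1 ± 41.7 CPM (6.44 ± 1.39, adjusted p = 0.0262), with ketogenic libraries from 0.538 to 111 CPM, and Cyp2e1, an abundant P450 that takes ethanol and ketones, from 5115 ± 1331 to 8527 ± 770.3 CPM (0.74 ± 0.17, adjusted p = 0.0232). The list passed the threshold without ketogenic 3 (adjusted p 0.0465 to 0.555 over the 12 fits), and without ketogenic 4 the median was -0.01 and camera's adjusted p 0.555. The call was lost for Cyp2b9 without control 1, 2, 3 or 6 (adjusted p 0.0155 to 0.0666 over the 12 fits). That of Cyp2e1 was lost without control 1 or 3 or ketogenic 6 (adjusted p 0.0124 to 0.0588 over the 12 fits). Cyp2b9 was not called with limma-voom or with no filter on low counts either (adjusted p 0.000122 to 0.205 over all its alternatives).

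None of the 45 nuclear-encoded genes of oxidative phosphorylation passed the edgeR test, at either adjustment. Ndufs1 was at 0.29, adjusted p = 0.117 and Ndufb3 at 0.48, adjusted p = 0.254, but camera called the list as higher (median log2 fold change 0.11, camera adjusted p = 0.0188, and adjusted p = 0.793 with an estimated correlation). Without ketogenic 4 the median was -0.05 and the sign of the list turned (adjusted p = 0.555), and without control 6 the call was lost too (adjusted p 0.000113 to 0.555 over the 12 fits). Of 13 transcripts of the mitochondrial genome, 0 rose, 1 fell and 12 did not pass the threshold. If adjusted over the list alone, 0 rose and 1 fell (median log2 fold change -0.25, camera adjusted p = 0.0201, and adjusted p = 0.548 with an estimated correlation). The gene that fell was mt-Cytb, from 6302 ± 1071 to 4179.9 ± 729 CPM (-0.59 ± 0.15, adjusted p = 0.0441), while mt-Nd4 was at -0.46, adjusted p = 0.164 and mt-Nd6, which lies on the other strand from its neighbours, at -0.27, adjusted p = 0.287. This list lost its call without control 1 or 4 or ketogenic 1, 2 or 4 (adjusted p 0.00186 to 0.0655). The call of mt-Cytb was lost without control 1, 2, 3 or 4 or ketogenic 1, 2, 3, 4 or 6 (adjusted p 0.0274 to 0.116).

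Of 21 genes of the integrated stress response, 0 rose, 1 fell and 20 did not pass the threshold. In the fit without ketogenic 4, 0 rose and 5 fell. When adjusted over the list alone, 1 rose and 2 fell (median log2 fold change -0.14, camera adjusted p = 0.408, and adjusted p = 0.842 with an estimated correlation). The folate enzyme gene Aldh1l2 fell from 2.11 ± 1.17 to 0.477 ± 0.375 CPM (-2.13 ± 0.48, adjusted p = 0.0233), and Vldlr and the serine synthesis gene Phgdh were at 1.44, adjusted p = 0.0657 and -2.55, adjusted p = 0.0866. None of 20 genes of the unfolded protein response was called over all genes. With p adjusted over the list alone, 0 rose and 1 fell, yet camera called the list as lower (median log2 fold change -0.47, camera adjusted p = 0.000222, and adjusted p = 0.548 with an estimated correlation). Its members with the smallest p were the chaperone genes Dnajc3 (-0.63, adjusted p = 0.0555) and Hsp90b1 (-0.71, adjusted p = 0.213) and the degradation factor gene Edem1 (-0.49, adjusted p = 0.0928). The call of Aldh1l2 was lost without control 3 or 5 or ketogenic 2, 3, 5 or 6 (adjusted p 0.00516 to 0.0611 over the 12 fits). A call of Vldlr was gained without ketogenic 2 (adjusted p 0.0478 to 0.146 over the 12 fits). That of Phgdh was gained without ketogenic 4 (adjusted p 0.0276 to 0.1797 over the 12 fits) and of Dnajc3 without control 4 or 5 or ketogenic 5 (adjusted p 0.0240 to 0.125 over the 12 fits). That of Edem1 was gained without ketogenic 5 (adjusted p 0.0251 to 0.189 over the 12 fits).

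The NRF2 antioxidant list held 0 calls among 18 genes by edgeR, over all genes and adjusted over the list alone. Its median was 0.183 and its mean -0.01, with a camera direction of higher (adjusted p = 0.744, and adjusted p = 0.918 with an estimated correlation); Me1 was at -0.56, adjusted p = 0.205, Slc48a1 at 0.32, adjusted p = 0.297 and Gsr at 0.197, adjusted p = 0.309. Without ketogenic 4 the sign of that median turned, to -0.103. Of 28 p53 targets, 3 rose, 0 fell and 25 did not pass the threshold. By p adjusted over the list alone, 4 rose and 1 fell (median log2 fold change 0.08, camera adjusted p = 0.0326, and adjusted p = 0.548 with an estimated correlation). Sulf2, a heparan sulfatase, rose from 4.58 ± 1.46 to 16.0 ± 7.43 CPM (1.80 ± 0.28, adjusted p = 0.00257), the proapoptotic gene Bbc3 from 4.67 ± 0.834 to 9.16 ± 1.99 CPM (0.97 ± 0.16, adjusted p = 0.00403) and Sesn1, a stress sensor, from 12.3 ± 2.06 to 19.4 ± 1.31 CPM (0.66 ± 0.12, adjusted p = 0.00550). Cdkn1a, the cell cycle inhibitor p21, was lower in all 6 ketogenic libraries than the control mean without passing the threshold (-1.44 ± 0.43, adjusted p = 0.0899), and passed it without ketogenic 4 (adjusted p 0.0428 to 0.179 over the 12 fits). The p53 list lost its call without control 1 or 2 or ketogenic 4 or 6 (adjusted p 0.00594 to 0.182; without ketogenic 4 the median was 0.02 and camera's adjusted p 0.182). No gene of the 23 senescence-associated factors was called at either adjustment (median log2 fold change 0.16, camera adjusted p = 0.370, and adjusted p = 0.842 with an estimated correlation). Plau was at 0.68, adjusted p = 0.185, Il1b at -1.03, adjusted p = 0.256 and Mmp12 at 1.72, adjusted p = 0.360. For that list, without ketogenic 4 the median was -0.03 and camera's adjusted p 0.780.

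Of 25 acute phase genes tested, 0 rose, 5 fell and 20 did not pass the threshold. Counted with p adjusted over the list alone, 1 rose and 11 fell (median log2 fold change -0.92, camera adjusted p = 5.35e-06, and adjusted p = 0.541 with an estimated correlation). The fibrinogen genes Fgg and Fgb fell from 5372 ± 1748 to 2780.3 ± 561 CPM (-0.95 ± 0.22, adjusted p = 0.0247) and from 6305 ± 1982 to 3344 ± 640.2 CPM (-0.91 ± 0.21, adjusted p = 0.0273), as did Fga, chosen after its value was seen (-0.92, adjusted p = 0.0362). Beside Hamp2, the hepcidin gene Hamp, also chosen after its value was seen, fell by 1.81 on the log2 scale (adjusted p = 0.0358). Saa1 and Orm2, looked up later, were at -1.97, adjusted p = 0.337 and -2.87, adjusted p = 0.152, with control libraries spread over 12.97 to 396 and 2.53 to 126 CPM, and both have near copies. The call was lost for Fgg without control 1 or 3 or ketogenic 1, 2 or 6 (adjusted p 0.00623 to 0.0674 over the 12 fits). That of Fgb was lost without control 1, 3 or 6 or ketogenic 1, 2 or 6 (adjusted p 0.00721 to 0.0739 over the 12 fits). Another was lost for Fga without control 1, 2, 3 or 6 or ketogenic 1, 2, 3 or 6 (adjusted p 0.0150 to 0.0882 over the 12 fits). That of Hamp was lost without control 1, 3, 4 or 6 or ketogenic 2, 3 or 5 (adjusted p 0.0130 to 0.0749 over the 12 fits).

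Of 22 interferon response genes, 1 rose, 0 fell and 21 did not pass the threshold. If adjusted over the list alone, 1 rose and 0 fell (median log2 fold change 0.28, camera adjusted p = 0.00285, and adjusted p = 0.548 with an estimated correlation). The proteasome subunit gene Psmb9 rose from 13.3 ± 2.59 to 24.0 ± 8.93 CPM (0.85 ± 0.21, adjusted p = 0.0364), and Usp18 and Ifit3 were at 0.73, adjusted p = 0.0925 and 0.71, adjusted p = 0.211. The list lost its call without ketogenic 4 (adjusted p 7.23e-06 to 0.0503 over the 12 fits, median 0.22 without that library). Of 27 cell cycle genes, 0 rose, 1 fell and 26 did not pass the threshold. When adjusted over the list alone, 0 rose and 1 fell (median log2 fold change 0.19, camera adjusted p = 0.0641, and adjusted p = 0.793 with an estimated correlation). The ribonucleotide reductase gene Rrm2 fell from 10.8 ± 4.94 to 3.88 ± 1.503 CPM (-1.48 ± 0.32, adjusted p = 0.0181), against the direction of the list, and Mcm5 and Mcm2 were at 0.54, adjusted p = 0.283 and 0.48, adjusted p = 0.367. Camera called the cell cycle list without control 5 or 6 or ketogenic 2 (adjusted p 0.000321 to 0.503 over the 12 fits; without ketogenic 4 the median was 0.06 and camera's adjusted p 0.503). For single genes, the call was lost for Psmb9 without control 2, 3, 4 or 5 or ketogenic 2, 3 or 5 (adjusted p 0.0135 to 0.0800 over the 12 fits). A call was gained for Usp18 without ketogenic 1 (adjusted p 0.0172 to 0.188 over the 12 fits). That of Mcm5 was gained without control 6 (adjusted p 0.0426 to 0.460 over the 12 fits).

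Clock genes moved in opposite directions. Of 19 tested, 2 rose, 3 fell and 14 did not pass the threshold. With p adjusted over the list alone, 7 rose and 5 fell; the median was -0.03, the mean 0.23, and camera's direction was higher (adjusted p = 0.744, and adjusted p = 0.844 with an estimated correlation). Npas2, a partner of BMAL1, fell from 5.27 ± 3.96 to 1.19 ± 0.507 CPM (-2.15 ± 0.52, adjusted p = 0.0364) and the repressor gene Cry1 from 13.7 ± 5.48 to 6.28 ± 1.63 CPM (-1.12 ± 0.24, adjusted p = 0.0185). Per3 and Tef, chosen after their values were seen, rose (2.12, adjusted p = 0.0365 and 0.84, adjusted p = 0.0478), and Dbp, Nr1d1 and Arntl, looked up later, were at 2.24, adjusted p = 0.106, at 0.89, adjusted p = 0.167 and at -1.10, adjusted p = 0.107. Without ketogenic 4, 3 of the 5 calls remained, and the median of the list was 0.07. All 5 remained with the length trend removed. The hour of tissue collection is not given in the sources used here. The call of Npas2 was lost without control 1, 2 or 3 or ketogenic 1, 2, 3, 4, 5 or 6 (adjusted p 0.0104 to 0.0857 over the 12 fits). That of Per3 was lost without control 1, 2, 3, 4 or 5 or ketogenic 1 or 6 (adjusted p 0.0311 to 0.0829 over the 12 fits). That of Tef ended without control 1, 2, 3, 4 or 5 or ketogenic 1, 2, 3, 4, 5 or 6 (adjusted p 0.0404 to 0.110 over the 12 fits). Nr1d1 passed without control 4 (adjusted p 0.00258 to 0.302). None of 21 immediate early and heat shock genes was called at either adjustment (median log2 fold change 0.33, camera adjusted p = 0.396, and adjusted p = 0.842 with an estimated correlation). Hspd1 was at 0.33, adjusted p = 0.145, Hspb1 at 0.73, adjusted p = 0.311 and Hspe1 at 0.39, adjusted p = 0.403, and without ketogenic 4 the median was 0.19 and camera's adjusted p 0.945.

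Of 19 pericentral genes, which are expressed near the central vein of the liver lobule, 4 rose, 0 fell and 15 did not pass the threshold. By p adjusted over the list alone, 5 rose and 0 fell (median log2 fold change 0.33, camera adjusted p = 7.96e-05, and adjusted p = 0.361 with an estimated correlation). Among those that rose were Cyp2e1 and Aldh3a2, given with other lists above, and Cyp1a2 from 316 ± 54.4 to 503 ± 97.6 CPM (0.67 ± 0.15, adjusted p = 0.0262). Of 19 periportal genes, expressed near the portal tract, 0 rose, 5 fell and 14 did not pass the threshold. Counted with p adjusted over the list alone, 0 rose and 10 fell (median log2 fold change -0.41, camera adjusted p = 4.08e-07, and adjusted p = 0.0717 with an estimated correlation). Cyp2f2 fell from 922 ± 143 to 604 ± 84.5 CPM (-0.61 ± 0.13, adjusted p = 0.0194) and Etnppl, which breaks down phosphoethanolamine, from 76.7 ± 26.0 to 30.8 ± 7.26 CPM (-1.32 ± 0.21, adjusted p = 0.00304), and the other calls were Hal, Sds and Gls2, which the amino acid list also holds. All 4 and all 5 calls remained without ketogenic 4. The call was lost for Cyp1a2 without control 1 or 3 or ketogenic 1, 2, 5 or 6 (adjusted p 0.0140 to 0.0733 over the 12 fits). Another was lost for Cyp2f2 without control 3 (adjusted p 0.0121 to 0.0577 over the 12 fits).

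Of 18 secreted proteins and regulators of hepatocytes, 0 rose, 4 fell and 14 did not pass the threshold. If adjusted over the list alone, 0 rose and 5 fell (median log2 fold change -0.34, camera adjusted p = 6.58e-06, and adjusted p = 0.0717 with an estimated correlation). The complement gene C9 fell from 630.4 ± 168 to 280.3 ± 79.1 CPM (-1.17 ± 0.21, adjusted p = 0.00629), Ambp from 2524 ± 442 to 1573 ± 178 CPM (-0.68 ± 0.13, adjusted p = 0.00930) and Gc, the vitamin D binding protein, from 6540.3 ± 749.96 to 4668 ± 623 CPM (-0.49 ± 0.12, adjusted p = 0.0376), and Serpinc1, the antithrombin gene, chosen after its value was seen, by 0.36 on the log2 scale (adjusted p = 0.0445). Leaving out 1 library ended the calls of Gc without control 1, 2, 3 or 6 or ketogenic 1, 2, 3, 5 or 6 (adjusted p 0.0156 to 0.0908 over the 12 fits). Serpinc1 lost its call in 11 of the 12 fits, all but that without ketogenic 4 (adjusted p 0.0334 to 0.111).

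Markers of other liver cells held 1 call in 6 lists. None of 22 macrophage and Kupffer cell markers was called at either adjustment; their median was 0.03 and mean 0.09, with a camera direction of lower (adjusted p = 0.744, and adjusted p = 0.922 with an estimated correlation), and Cd9, Trem2 and Mpeg1 were at -0.61, adjusted p = 0.167, at 0.80, adjusted p = 0.492 and at -0.19, adjusted p = 0.562. None of 18 lymphocyte markers was called at either adjustment (median -0.00, mean 0.07, camera direction higher, adjusted p = 0.744, and adjusted p = 0.918 with an estimated correlation). Gzmb was at -1.19, adjusted p = 0.185, Cd4 at 0.79, adjusted p = 0.236 and Cd79a at 0.67, adjusted p = 0.244. Neutrophil markers, with 0 of 5 called, were higher as a list by camera (median 0.69, camera adjusted p = 0.0395, and adjusted p = 0.548 with an estimated correlation). S100a8 was at 0.98, adjusted p = 0.211, S100a9 at 0.81, adjusted p = 0.319 and Csf3r at 0.35, adjusted p = 0.409. The neutrophil list lost its call without control 1, 2, 3, 4 or 5 or ketogenic 4, 5 or 6 (adjusted p 0.0153 to 0.182 over the 12 fits). Of 21 stellate cell and fibrosis genes 0 were called; the median was -0.11 and the mean -0.17, while camera's direction was higher (adjusted p = 0.905, and adjusted p = 0.964 with an estimated correlation) and fry's lower, and Colec11, Tgfbi and Acta2 were at 0.37, adjusted p = 0.401, at 0.23, adjusted p = 0.475 and at -0.98, adjusted p = 0.481. Endothelial markers were higher as a list, with positive values in all 16 members, 0 called at either adjustment (median 0.16, camera adjusted p = 0.0103, and adjusted p = 0.541 with an estimated correlation), Vwf at 0.31, adjusted p = 0.231, Pecam1 at 0.19, adjusted p = 0.244 and Bmp2 at 0.21, adjusted p = 0.401, a call lost without control 1 (adjusted p 0.000467 to 0.0524). Of 12 cholangiocyte markers, Krt23 rose and 11 did not pass. When adjusted over the list alone, 1 rose and 0 fell (median 0.11, camera adjusted p = 0.574, and adjusted p = 0.842 with an estimated correlation). Sox9 was at -0.48, adjusted p = 0.203. Without ketogenic 4 the medians were -0.12 for macrophage, -0.08 for lymphocyte, 0.36 for neutrophil, -0.16 for stellate, 0.198 for endothelial and -0.07 for cholangiocyte markers. Cd9 passed the threshold without ketogenic 4 (adjusted p 0.00786 to 0.290 over the 12 fits). The log2 fold change of Acta2 ran from -1.19 to 0.098 over these fits. Control 6 was at 26.4 CPM in Acta2, against 2.60 to 4.54 CPM in the other controls.

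Of 20 liver genes known to be higher in males, 1 rose, 1 fell and 18 did not pass the threshold. With p adjusted over the list alone, 1 rose and 3 fell (median -0.21, camera adjusted p = 0.366, and adjusted p = 0.842 with an estimated correlation); Cyp4a12a rose (0.91 ± 0.21, adjusted p = 0.0247), Cyp2u1 fell (-0.69 ± 0.17, adjusted p = 0.0380) and Serpina12 was at -1.77, adjusted p = 0.0555. Of 15 genes known to be higher in females, 2 rose, 1 fell and 12 did not pass the threshold. By p adjusted over the list alone, 5 rose and 3 fell (median 0.25, camera adjusted p = 0.141, and adjusted p = 0.548 with an estimated correlation). Beside Cyp2b9, Tox rose from 2.13 ± 0.499 to 8.23 ± 1.90 CPM (1.95 ± 0.197, adjusted p = 0.000177) and the neurotrophin receptor gene Ntrk2 fell from 3.05 ± 2.55 to 0.430 ± 0.221 CPM (-2.81 ± 0.63, adjusted p = 0.0239). None of 4 sex chromosome genes was called (median -0.13, camera adjusted p = 0.366, and adjusted p = 0.729 with an estimated correlation), and the Y-linked genes Ddx3y, Kdm5d and Uty were at -0.33, adjusted p = 0.225, at -0.16, adjusted p = 0.714 and at -0.103, adjusted p = 0.788. Xist, which female cells express, had 0 to 5 counts per library, against 1343 to 2547 of Ddx3y. By these genes the libraries of both diets came from males. The call was lost for Cyp4a12a without control 1 or 2 or ketogenic 2, 3 or 5 (adjusted p 0.00812 to 0.0587 over the 12 fits). That of Ntrk2 was lost without ketogenic 2, 4, 5 or 6 (adjusted p 0.00505 to 0.0612 over the 12 fits). Likewise it was lost for Cyp2u1 without control 1, 3, 4 or 6 or ketogenic 3, 4, 5 or 6 (adjusted p 0.0142 to 0.102 over the 12 fits). A call was gained for Serpina12 without control 6 or ketogenic 1 (adjusted p 0.0442 to 0.105 over the 12 fits).

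Erythrocyte genes held 0 calls among 6 over all genes. Counted with p adjusted over the list alone, 1 rose and 0 fell (median 0.42, camera adjusted p = 0.188, and adjusted p = 0.692 with an estimated correlation). Bpgm was at 0.44, adjusted p = 0.0520, Alas2 at -0.42, adjusted p = 0.297 and Hbb-bt at 0.56, adjusted p = 0.520, and without ketogenic 4 the median was 0.12 and camera's adjusted p 0.507; Bpgm passed without ketogenic 1 (adjusted p 0.0275 to 0.113 over the 12 fits). Of 4 tested genes of pancreas and adipose tissue, Cfd rose and 3 did not pass. If adjusted over the list alone, 1 rose and 0 fell (median 0.19, camera adjusted p = 0.175, and adjusted p = 0.548 with an estimated correlation). Car3 was at 0.36, adjusted p = 0.616 and Cela2a at -0.15, adjusted p = 0.877. The adipocyte genes Adipoq, Retn and Plin1 together had 10 counts in the 6 ketogenic libraries, against 1987 counts of Cfd, but Fabp4, looked up later, which adipocytes and other cells express, had 1609 counts in the control and 2634 in the ketogenic libraries, 960 of these in ketogenic 4. None of 45 cytosolic ribosomal protein genes was called at either adjustment, while camera called the list as lower (median -0.15, camera adjusted p = 0.000593, and adjusted p = 0.729 with an estimated correlation). Rpl30 was at -0.37, adjusted p = 0.403, Rpl4 at -0.21, adjusted p = 0.442 and Rplp0 at -0.25, adjusted p = 0.486. These short transcripts were high in ketogenic 4, and without that library 13 of them were called lower, at a median of -0.37 (camera adjusted p = 2.40e-19), Rpl30 among them (adjusted p 0.0244 to 0.585 over the 12 fits).

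**Figure D3:**
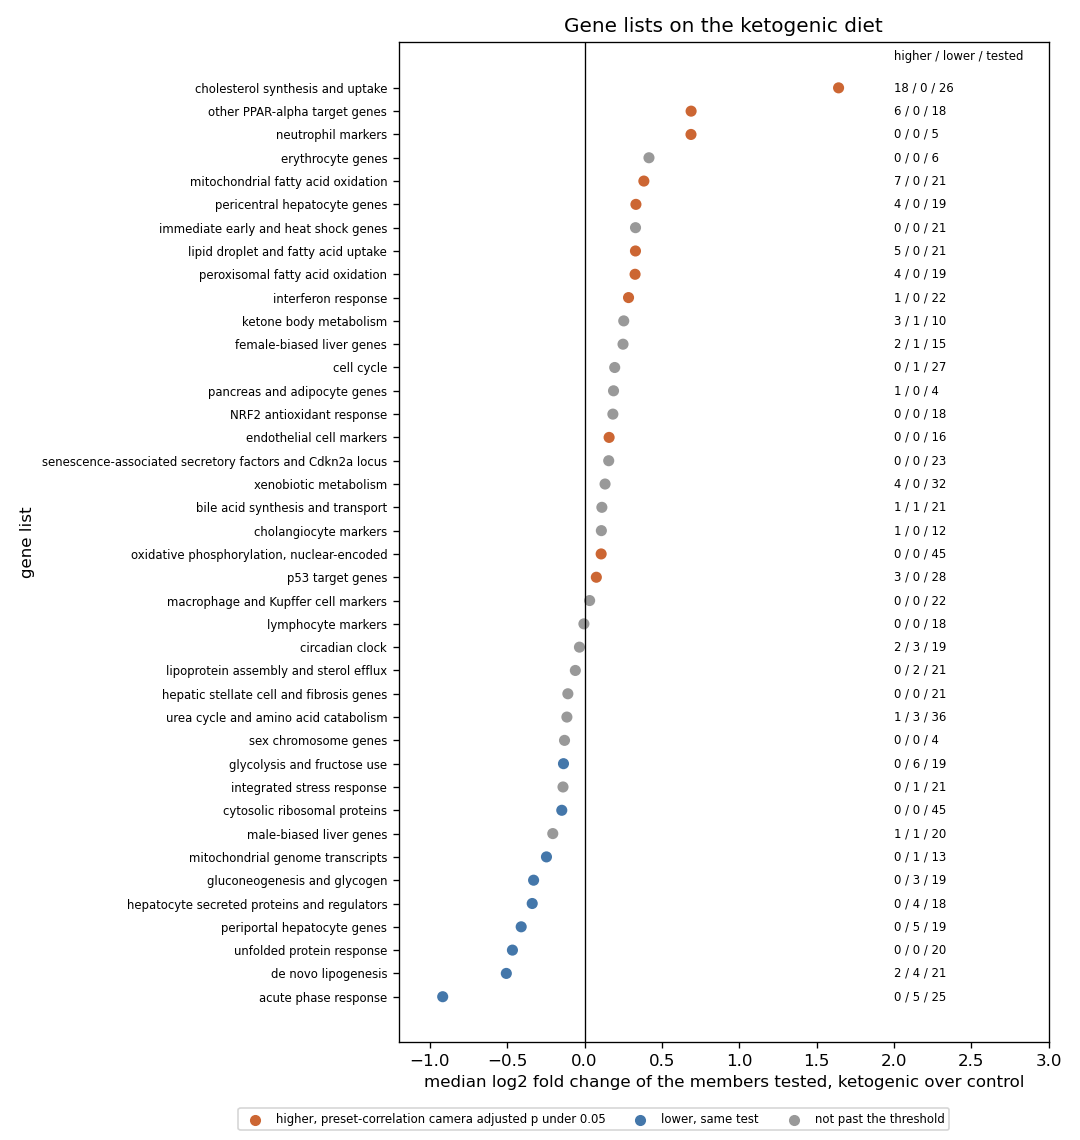
Median log2 fold change, ketogenic over control, of the tested members of each of the 40 gene lists, 1 point per list, coloured by camera's test with the preset correlation (orange higher, blue lower, grey not past the threshold), with the numbers of members called higher, called lower and tested. Cholesterol synthesis and uptake has the highest median (1.64) and the acute phase list the lowest (-0.92).

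Of the 40 lists, 11 were called higher and 9 lower by camera with the preset correlation, 0 with the correlation estimated per list, and 9 by fry, with 6 higher and 3 lower. By unadjusted p under 0.05, camera with an estimated correlation called 5 lists. Fry asks whether the genes of a list move in a common direction and does not compare them with other genes.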

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

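Of the tests given here, 3 were chosen only after the result was seen: that of the clock score without ketogenic 4, that of the clock difference in SD, and that of cholesterol against clock scores. So were the fits with the length trend removed and the numbers of splits per list. The other tests had their outcomes written down before the value they measure was computed, though after ketogenic 4 had been seen to stand apart. Within each diet, each reported gene of the naming rule and each library measure was searched for a library far from the other 5. For genes the gaps were taken on log2 CPM, so they cannot be read from the CPM printed below. A library whose gap to the nearest was over 0.625 of the range was found in 29 of 276 groups of 6 (10.5%). Chance gives about 1 in 20 for independent, normally distributed groups. These groups come from the same libraries and hold correlated genes, so the excess is no test. Ketogenic 4 was that library in 11 of them, which include the correlation to its group by which it was described as standing apart.

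Ketogenic 4 lay far from the other 5 ketogenic libraries in Acadm at 845 CPM (others 603 to 665), Hal at 108 CPM (others 197 to 243) and Gls2 at 89.9 CPM (others 148 to 185). The same held for Plau at 7.003 CPM (others 2.78 to 3.28), Trem2 at 12.6 CPM (others 2.60 to 3.74), Kdm5d at 8.09 CPM (others 13.6 to 15.7) and Uty at 8.47 CPM (others 12.3 to 13.3). It also did so in library size at 30.9 M counts (others 32.6 to 33.5), haemoglobin share at 0.00914% (others 0.00301 to 0.00456), score on principal component 1 at -77.1 (others -15.8 to 14.6) and median correlation to its group at 0.951 (others 0.978 to 0.984).

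Transcript length tracked the deviation of this library, with a Spearman rho across genes of -0.551, larger in size than in every other library (-0.325 to 0.354), and a difference in RNA quality is a candidate explanation. A trend on GC content is argued against by a partial rho of 0.0360 given length, and a larger share of all other cell types by endothelial markers, whose median deviation with the length trend removed was 0.0741 against up to 0.223 in the other ketogenic libraries. Stellate and cholangiocyte markers stayed above the others (0.62 against 0.24, and 0.98 against 0.21), so more of these cells in the piece of liver stays open, and no biological explanation was tested.

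A clock score, the mean log2 CPM of 10 genes such as Dbp and Per3 minus that of 6 such as Arntl and Npas2, was -0.99 ± 1.14 on the control and 1.00 ± 1.03 on the ketogenic diet (mean ± SD, n = 6 each, exact permutation p = 0.00649). For RNA quality of ketogenic 4, the test written first left the calls of single clock genes open: 3 of the 5 stayed past the threshold without that library (Npas2 and Tef did not), where at most 1 loss was to argue against it and fewer than 2 left were to fit. Npas2 and Tef lost their calls in 9 and 11 of the leave-one-out fits. Their log2 fold changes there were -2.36 to -1.71 and 0.69 to 0.94. The score was put together after clock genes were seen to differ. Its p without ketogenic 4 (exact permutation p = 0.0130 over 462 splits) is therefore no support. Its difference was 1.98 without that library and 1.99 with it, and all 5 called clock genes stayed called with the length trend removed. These values were also looked at after the result was seen. They show that the difference in the score did not come from that library alone, and leave open whether its RNA quality had a part. With all libraries the difference was 1.83 pooled SD, and a different hour of collection may give such a difference, as may the diet. The labels give no hours, so hour and diet cannot be told apart. In both diets replicates 2 and 3 had the lowest clock scores and replicate 6 the highest. What the replicate numbers stand for is not given.

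Of the 18 genes of cholesterol synthesis and uptake called, 15 remained without ketogenic 4 and 18 with the length trend removed, which argues against the RNA quality of that library as the whole cause. A cholesterol score (mean log2 CPM of the list) had a correlation with the clock score of r = 0.689 among the 6 control libraries (exact permutation p = 0.144, adjusted 0.289; rho = 0.543, exact p = 0.297), and of r = 0.441 without the 2 farthest libraries. Among the 6 ketogenic libraries it had r = 0.0628 (exact permutation p = 0.889, adjusted 0.889; rho = 0.0286, exact p = 1) and r = -0.566 without the 2 farthest, and neither correlation passed the threshold. The diet difference of the cholesterol score was 1.53 ± 0.27 (SE), and 1.12 ± 0.36 with the clock score in the model. With 6 libraries per diet, whether part of the rise follows the clock difference stays open, as does the diet itself.

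Among control libraries, control 6 lay far from the other 5 in Acads at 145 CPM (others 179 to 189), Ndufs1 at 86.0 CPM (others 107 to 115) and Colec11 at 25.8 CPM (others 39.4 to 48.0). It did so in Acta2 at 26.4 CPM (others 2.60 to 4.54), Gc at 8012 CPM (others 5997 to 6512) and in median correlation to its group at 0.972 (others 0.979 to 0.981). Control 4 did so in Pnldc1 at 3.39 CPM (others 0.564 to 1.05) and Ttbk1 at 2.67 CPM (others 5.99 to 9.34), and control 3 in Plau at 1.24 CPM (others 2.16 to 2.89) and Pecam1 at 29.4 CPM (others 33.1 to 35.1). Control 5 was apart in Vldlr at 3.49 CPM (others 1.47 to 1.98), and control 1 in Hspe1 at 165 CPM (others 109 to 126) and in its length rho at -0.325 (others 0.0659 to 0.246). Of the ketogenic libraries, ketogenic 6 was apart in Slc35f2 at 10.5 CPM (others 4.56 to 5.78), Npas2 at 0.271 CPM (others 1.03 to 1.73), Mpeg1 at 103 CPM (others 70.9 to 75.4) and Csf3r at 6.53 CPM (others 3.60 to 4.40), and ketogenic 1 in Cyp2f2 at 447 CPM (others 593 to 695).

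Among 100 of the 462 splits of the 12 libraries into 6 and 6, the real one included, 1 gave as many genes as the 529 past the threshold, and the highest of the others gave 89. Chance is thus an unlikely source of that count, with 1 in 100 the lowest share these splits can give. For the number of lists, 6 splits gave at least the 20 that camera called with the preset correlation (highest other 23, median other 13), so chance cannot be excluded for it. List by list, the number of the 100 splits with a camera p as small as the real one was 1 for cholesterol synthesis and uptake, hepatocyte secreted proteins and regulators; 2 for mitochondrial fatty acid oxidation; 4 for periportal genes; 5 for other PPAR-alpha targets, lipid droplets and fatty acid uptake; 6 for pericentral genes; 9 for peroxisomal oxidation, glycolysis and fructose use; 14 for gluconeogenesis; 16 for acute phase; 17 for the mitochondrial genome; 22 for neutrophil markers, endothelial markers; 23 for the unfolded protein response; 25 for p53 targets; 28 for interferon response; 30 for lipogenesis; 58 for ribosomal proteins; 67 for oxidative phosphorylation.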

How the results depend on the processing

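Fits with the length trend removed were added after the data were seen. Of the 529 genes called, none changed sign in those of the 25 alternative fits that tested it. With at least 1 CPM in 6 samples 489 of them were tested, without the 10 most abundant genes 528, and in the others all. These fits use the same libraries, or all but 1 of them. A called gene is unlikely to change sign there, so this is no separate support. Genes higher, lower and in all numbered 328, 201 and 529 in the edgeR fit. They were 304, 192 and 496 with limma-voom, 325, 206 and 531 with RLE factors, 344, 194 and 538 without the 10 most abundant genes, 327, 192 and 519 with at least 1 CPM in 6 samples and 279, 147 and 426 with no filter. DESeq2 gave 579, 422 and 1001, with 130 lower by a log2 of 1 or more. There were 684, 634 and 1318 with 1 surrogate variable, 448, 127 and 575 with library size only. Stricter settings gave 140, 57 and 197 at an adjusted p under 0.01 (89 and 37 by a log2 of 1 or more) and 159, 71 and 230 against a 1.2-fold change. With the length trend removed there were 437, 323 and 760, which kept 510. Stricter settings give fewer calls by construction, and for the other shifts the cause was not tested.

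Over all genes, the shared replicate numbers gave no sign of pairs: correlations of same-numbered residuals ran from -0.291 to 0.336 with a mean of 0.0169, as high in 303 of 720 pairings, and 2 of 6 controls correlated best with their own number. Single genes can differ from this: Pdk4 and Txnip, picked after their values were seen, had r = 0.916 and 0.836 between same-numbered libraries (exact p = 0.0111 and 0.0347 over 720 pairings, rho = 0.829 and 0.714, exact p = 0.0583 and 0.136), and what the numbers may stand for stays open. The clock score, also looked at after its values were seen, was lowest in replicates 2 and 3 and highest in replicate 6 in both diets. With the replicate block 175, 93 and 268 genes were called, and 245 of the 529 were kept. With the length trend removed as well there were 287, 177 and 464. Camera with the block called 12 lists higher and 9 lower, adding the cell cycle list (adjusted p = 0.0161).

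Leaving out 1 library gave 319 (control 3) to 761 (ketogenic 4) genes in all, and 336 without ketogenic 6. Genes higher numbered 213 (control 3) to 445 (ketogenic 4), with 218 without ketogenic 6. Genes lower numbered 106 (control 3) to 316 (ketogenic 4), with 121 without control 1 and 133, 129 and 118 without ketogenic 2, 3 and 6. Lists higher numbered 7 (ketogenic 4) to 12 (ketogenic 2 or 3). Without ketogenic 4, 7 lists were lower and the direction of oxidative phosphorylation reversed (adjusted p = 0.555). Adjusted p over these fits ran from 0.00212 to 0.1996 for lipogenesis and from 0.00850 to 0.0660 for gluconeogenesis. They ran from 0.0212 to 0.415 for the urea cycle list, 0.0465 to 0.555 for xenobiotic metabolism, 0.000113 to 0.555 for oxidative phosphorylation. For the mitochondrial genome they were 0.00186 to 0.0655, 0.00594 to 0.182 for p53 targets and 7.23e-06 to 0.0503 for interferon response. Ranges were 0.000321 to 0.503 for cell cycle, 0.0153 to 0.182 for neutrophil and 0.000467 to 0.0524 for endothelial markers. Each of these crossed the threshold without the libraries named with the list. The other 29 lists kept their side of the threshold in all 12 fits.

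With the inter-gene correlation estimated, camera called 0 lists higher, 0 lower and 0 in all. The adjusted p of the 20 was 0.0717 (hepatocyte secreted proteins and regulators, periportal genes), 0.125 (cholesterol synthesis and uptake), 0.330 (mitochondrial fatty acid oxidation), 0.335 (other PPAR-alpha targets), 0.361 (pericentral genes), 0.363 (lipid droplets and fatty acid uptake, peroxisomal oxidation), 0.419 (gluconeogenesis), 0.502 (glycolysis and fructose use), 0.541 (acute phase, endothelial markers), 0.548 (the mitochondrial genome, neutrophil markers, the unfolded protein response, p53 targets, interferon response, lipogenesis), 0.729 (ribosomal proteins), 0.793 (oxidative phosphorylation).

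Fry called 9 lists, and its adjusted p was 0.0538 (gluconeogenesis), 0.123 (endothelial markers), 0.131 (acute phase), 0.179 (neutrophil markers, lipogenesis), 0.184 (the mitochondrial genome), 0.203 (the unfolded protein response, p53 targets), 0.252 (interferon response), 0.506 (ribosomal proteins), 0.624 (oxidative phosphorylation) for the lists among camera's 20 that it did not call. It called none of the other 20 lists (lowest adjusted p 0.0869, for ketone body metabolism). With library size only the neutrophil list was lost (adjusted p = 0.0644). With at least 1 CPM in 6 samples the neutrophil (0.0838) and p53 lists (0.0671) were lost and the female-biased list was gained (0.0161), while the pancreas and adipocyte list had too few members. RLE factors changed no list, and removal of the length trend none of the 20. No share of counts changed its side of the threshold with the counts of filtered genes as denominator. The causes were not tested.

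Of 120 named genes that were called, 120 stayed called with DESeq2, 110 with limma-voom, 112 with library size only, 96 with no filter, 75 with the block and 116 with the length trend removed. Among those lost were Cfd, Sds, Cyp2b9, Psmb9, Npas2, Ntrk2, Gpt2, Tef and Cpb2 with limma-voom, Gls2, Sds, mt-Cytb, Cyp2u1, Serpinc1, Rps27rt and F12 with library size only and mt-Cytb, Acadvl, Hamp and Serpinc1 with the length trend removed. No filter ended the calls of Angptl8, Cyp2c70, Cyp2b9, mt-Cytb, Npas2, Gc, Ntrk2, Acadvl, Cyp4a10, Fdps, Mvd, Hamp, Per3, Tef, Serpinc1, Mup9, Rps27rt, Aars2, Hars2, F7 and F12, among others. Leaving out 1 library kept 83 (control 3) to 111 (ketogenic 4), and no gene reversed. These fits hold fewer libraries, so a call near the threshold can be lost at a similar fold change. Tef, for example, lost its call in 11 of them at log2 fold changes of 0.69 to 0.94. Genes near 1 CPM, such as Mogat1, Trhde and Aldh1l2, rest on few counts per library. At this depth a log2 change of 1 was recovered in 74 of 100 simulated genes, so a gene that was not called is not shown to be unchanged.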

Other observations

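The tests of GO terms and the genes in this part were chosen after the results were seen. Beyond the fixed lists, genes that rose were enriched for ligase activity, with 15 genes against 2.86 expected by chance (adjusted p = 3.86e-05). These included some genes of mitochondrial aminoacyl-tRNA ligases, but the narrower terms did not pass: aminoacyl-tRNA ligase activity had 5 of 40 genes (adjusted p = 0.212) and tRNA aminoacylation 3 of 13 (adjusted p = 0.235). Aars2 rose by 0.36 (adjusted p = 0.0390), Hars2 by 0.41 (0.0110), Tars2 by 0.51 (0.0153) and Vars2 by 0.54 (0.00293) on the log2 scale. The call of Aars2 held in only 2 leave-one-out fits, those without ketogenic 4 and without ketogenic 6 (adjusted p 0.0190 to 0.0909 over the 12 fits).

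Genes that fell were enriched for blood coagulation, with 6 genes (C9, Cpb2, F12, F7, Hgfac and Serpinc1) against 0.647 expected (adjusted p = 0.00742). Of these, C9, a complement gene, and Serpinc1 are also on the fixed list of hepatocyte proteins. The fibrinogen genes, which fell too, are not among the 6. F7, which encodes clotting factor VII, fell by 0.47 on the log2 scale (adjusted p = 0.0226), F12 by 0.35 (0.0396), Cpb2 by 0.60 (0.0450) and Hgfac by 0.62 (0.0163). Calls were lost for F7 without control 1 or 3 or ketogenic 3 or 6 (adjusted p 0.0146 to 0.0673 over the 12 fits). That of F12 was lost without control 1, 2, 3, 4 or 6 or ketogenic 1, 2, 3 or 6 (adjusted p 0.0217 to 0.1001 over the 12 fits). That of Cpb2 was lost without control 1, 2, 3, 4 or 6 or ketogenic 1, 2, 3 or 6 (adjusted p 0.0181 to 0.118 over the 12 fits). Heparin binding was enriched among falls too, with 6 genes against 0.956 expected (adjusted p = 0.0463). In all, 29 terms passed among rises and 3 among falls in 3968 hypergeometric tests of 1984 terms, many of them sharing genes. The test treats genes as independent of each other, though genes of a term can move together in the same livers. Its p-values may therefore be too small.

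Mup9, of the major urinary proteins, rose from 5.73 ± 5.09 to 50.9 ± 36.7 CPM (log2 fold change 3.15 ± 0.68, adjusted p = 0.0232), a value that close copies can share, and lost its call without control 1 or 2 (adjusted p 0.0104 to 0.0554 over the 12 fits). Rps27rt, a retrotransposed copy of a ribosomal protein gene, fell from 53.9 ± 28.4 to 13.8 ± 8.26 CPM (-1.97 ± 0.48, adjusted p = 0.0391), and lost its call without control 1, 2, 4 or 5 or ketogenic 2, 3, 5 or 6 (adjusted p 0.0156 to 0.0846). Bounds for adipose tissue carried into the samples were also written, in part after counts were seen, and are left unweighed here. Of Cfd, Cidec, Mogat1, Cd36 and Pparg, genes that adipocytes also express, all 5 rose, and all 5 remained called without ketogenic 4. The counts of Adipoq, Retn and Plin1 together came to 0.503% of those of Cfd in the ketogenic libraries. Control and ketogenic libraries held 2 and 3 counts of Adipoq, 1 and 2 of Retn, 5 and 5 of Plin1, 35 and 1987 of Cfd and 1609 and 2634 of Fabp4, the last with 960 in ketogenic 4.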
